A study of Mus musculus with 5 samples.

How the data were processed

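Kidneys of 5 mice after ischemia-reperfusion injury were measured by single-cell RNA sequencing, mice 1 and 2 at 48 h and mice 3, 4 and 5 at day 10. Each mouse is 1 library and 1 replicate, no uninjured kidney is among the samples, and the labels give no batch and no sex. Libraries were made with the 10x Genomics Single Cell 3' v3.1 chemistry. The submitters' processing notes list Cell Ranger 6.0.2, Seurat 4.0.5 and the mm10 mouse genome, while the headers of the matrices give Cell Ranger 6.0.0, and which of them made the files was not settled here.

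The authors deposited, per library, a matrix of raw UMI counts per gene and barcode over 32285 genes, with gene and barcode lists, and a table of 23797 cells for the whole series. That deposited table gives each cell's UMI count and gene count, its percent of mitochondrial UMIs, a cell type label (18 labels), a cluster (16 clusters) and a pair of embedding scores from the authors (UMAP coordinates, not used here). The counts and percents of the table were checked against the matrices and were equal for every cell. The authors' cell filter was recovered from the values: at least 1000 UMIs, over 300 and under 7000 genes and under 35% mitochondrial UMIs, with 0 barcodes that differ from the table. No step that removed doublets or free RNA was visible in the table. The libraries held 8583, 6376, 8669, 5434 and 8105 barcodes (mice 1 to 5), of which 4895, 3720, 5912, 3909 and 5361 were kept, with a median of 5823, 6260, 10328.5, 11750 and 10448 UMIs per cell. The median over all cells was thus higher at day 10, although it was lower in the thick ascending limb, in the distal tubule and principal cells and in immune cluster 5. Summed UMIs per library were 60583527, 45887945, 78351722, 57375234 and 72085975. Gene names were taken from the files, with GENCODE M21 used for former symbols and for symbols shared by several gene IDs; Mx1 of the interferon list is not in the files.

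The 18 labels were merged into parent types, with states (injured, cycling) inside their parent type. A type was tested where each library held at least 20 of its cells: immune cells, endothelial cells, proximal tubule, distal tubule and principal cells (distal convoluted and connecting tubule, principal cells and injured distal cells), thick ascending limb and TEC-labelled tubule as the 6 main types, and descending thin limb, intercalated cells and interstitial cells. Podocytes and red blood cells had too few cells. The clusters of the deposited clustering inside the immune label were tested apart, a choice made after the data were seen; cluster 12 had too few cells for genes.

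Raw UMIs were summed per mouse and type and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, quasi-likelihood F test of day 10 against 48 h and Benjamini-Hochberg adjustment over the genes of a type, with a threshold of 0.05. The standard error is the size of the log2 fold change over the root of F. CPM in the text are of raw totals, whereas fold changes use TMM factors, so the ratio of mean CPM can differ from the fold. For genes given here in the thick ascending limb and immune cluster 5 it was above the fold for rises and below it for falls. Cell numbers per label were tested with the same edgeR test, with the library's total of kept cells as offset. The difference of the time effect between proximal tubule and thick ascending limb was the interaction term of an edgeR fit with mouse as a block. Of 38 gene lists, those with at least 5 genes past the filter were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a type. With the correlation estimated per list, no list passed in any type, and that adjusted p stands beside each call. The lists, the tests, the markers and the rule for named genes were fixed before the data were examined. The injury and failed-repair lists hold proximal tubule markers and were used unchanged in the other types.

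The rule for named genes took, per main type, the 10 largest rises and 10 largest falls among genes past the threshold, with CPM that do not overlap between the groups, an average log2 CPM of 5 or more and a level in the type of at least 0.2 times that in the rest of the cells, leaving out gene models and mitochondrial genes (5 and 5 for all cells summed, 3 and 3 for the other types). Immune cluster 0, not a main type and chosen after the data were seen, was also given 10 and 10. The rule added up to 3 rises and 3 falls per fixed list, and a fixed set of proximal tubule, macrophage, fibroblast and endothelial genes. Some genes the rule took are left out of the text, among them hemoglobin genes and genes of the immune label that are given for all cells or for an immune cluster. A fold against a group with no count is a lower bound with 3 counts as the floor of that group. With 1 to 3 counts in a group the ratio of the CPM of the summed groups is given with its exact Clopper-Pearson interval. Floors and intervals cover counting error only.

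Alternatives were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), no filter on low counts, equal numbers of cells and counts per library, cells with at least 500 genes and at most 25% mitochondrial UMIs, cells without a state label, genes not under 0.2 times the rest, own clusters, fry and an estimated correlation for the lists, TMM factors, limma on logit shares with 0.5 cells added and compartment totals for the shares, equal weights of the cell types for the summed cells, and each mouse left out in turn. Own clusters were Leiden clusters (leidenalg 0.10.2) at resolution 1 on 30 principal components of 2000 variable genes with 20 neighbours, named by the fixed markers. Doublets were scored with scrublet in scanpy 1.11.5 at an expected 6%; its automatic threshold marked between 0.0613% and 2.48% of cells, so leaving out the 6% of cells of each library with the highest scores was added after the data were seen, as was leaving out the 13 mitochondrially encoded genes.

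The tests were tried on simulated negative binomial counts with the real means and totals. The spread was the common dispersion of each type, the same for all its genes, and genes were drawn independently. Changed genes were picked above a minimum level. For the shares the dispersion was set by hand. For the difference between the segments the thick ascending limb dispersion served both, with mouse effects of a set size. Recovery in the real data, where genes differ in spread, can therefore differ. Of 100 genes changed 4-fold 74% were recovered in the TEC-labelled tubule and 99 to 100% in the other main types and the summed cells; of 100 genes changed 2-fold 19% were recovered in the TEC-labelled tubule, 30% in the summed cells and 46 to 78% in the other types, with 4 to 8 calls among unchanged genes per type. A 4-fold change of a label's share was called in 81% of 100 draws. Of simulated differences between the segments 28% were recovered at 2-fold and 97% at 4-fold. A gene without a call can therefore still differ by 2-fold.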

Results

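Single cells of 5 mouse kidneys were compared between 48 h (mice 1 and 2) and day 10 (mice 3, 4 and 5) after ischemia-reperfusion injury (IRI), so every change is between an early and a late time and none is against an uninjured kidney. Fold changes are day 10 relative to 48 h, SE is the standard error of a log2 fold change, CPM is counts per 1000000 of a cell type's summed UMIs averaged over mice, and every adjusted p of a gene is from the edgeR quasi-likelihood test with Benjamini-Hochberg correction.

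With all cells of a library summed, thick ascending limb identity and S-phase genes were lower at day 10, and the largest changes included macrophage, matrix and neutrophil genes. Apoe, a lipid carrier of macrophages, rose from 583 to 14900 CPM (log2 fold change 4.55, SE 0.38, adjusted p = 0.0207). The monocyte attractant Ccl8 (log2 fold change 8.03), the elastase Mmp12 (5.33), the complement component C4b (3.98), the macrophage receptor Fcrls (3.81) and the matrix proteins Tnc (4.35) and Postn (3.95) also rose. Retnlg and S100a9, products of neutrophils, fell (log2 fold change -5.35 and -4.38), as did Wfdc21 (-4.81), Stfa2l1 (-4.61) and Cstdc4 (-4.44). Among 13 thick ascending limb identity genes 6 fell over all genes tested, including the inositol transporter Slc5a3 (-2.31), the urinary protein Umod (-1.92) and the phosphatase inhibitor Ppp1r1a (-1.82). Adjusted over the list alone 10 of the 13 fell (camera adjusted p = 3.26e-07, 0.327 with an estimated correlation). Of 25 S-phase genes 9 fell, among them Rrm2, a subunit of ribonucleotide reductase (-1.62), and 25 when adjusted over the list alone. The S-phase list had camera adjusted p = 2.85e-19 and 0.299 with an estimated correlation. In all, 321 of 17507 genes changed, 208 of them up, and 45.4% of tested genes had CPM that did not overlap between the groups, against a chance share of 20% for 2 against 3 mice. This count fell to 0 without mouse 2 or without mouse 3, to 39 without mouse 1 and to 94 without mouse 5, and rose to 436 without mouse 4. With cell types at equal weights and limma trend in place of edgeR, Umod and Ppp1r1a no longer passed.

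The make-up of the kept cells differed between the times. Barcodes with at least 35% mitochondrial UMIs are not among them. They were 28.3 and 25.8% of barcodes in the 48 h mice and 22.0, 14.4 and 22.6% in the day 10 mice, and their effect on the shares was not tested. Proximal tubule cells labelled as cycling were 2.35% of cells at 48 h (SD 0.0554 over 2 mice) and 0.563% at day 10 (SD 0.0968 over 3 mice), a log2 fold change of -2.05 (SE 0.40, adjusted p = 0.00195). The Lrp2-negative S2/3 proximal tubule label fell from 5.65% to 1.98% (log2 fold change -1.50, SE 0.44, adjusted p = 0.0227) and the red blood cell label from 0.553% to 0.0925% (-2.44, SE 0.69, adjusted p = 0.0227). Cells of the Lrp2-negative S2/3 label had a median of 1990 UMIs, against 16602.5 for the Lrp2-positive S2/3 label. A subtype and a low depth were not told apart here. Interstitial cells, the fibroblast and pericyte label, rose from 2.13% (SD 0.312) to 5.55% (SD 1.97; log2 fold change 1.38, SE 0.44, adjusted p = 0.0297). The thick ascending limb went from 11.6% to 5.85% (log2 fold change -0.99, adjusted p = 0.0771), which passed when subtypes were merged into 11 types (adjusted p = 0.0285), a family chosen after the data were seen. Immune cells were 25.6% (SD 9.17) at 48 h and 40.1% (SD 3.40) at day 10, which did not pass (log2 fold change 0.65, adjusted p = 0.199). Injured proximal tubule cells were 7.36% (SD 6.64) and 3.69% (SD 2.15), a difference smaller than the spread at 48 h (adjusted p = 0.199). Of 18 labels 4 changed in share, and 1 did with TMM factors over cell types or with limma on logit-transformed shares. Leaving out a mouse in turn left between 1 (without mouse 1) and 5 labels (without mouse 2), and without mouse 1 the share of injured proximal tubule cells was higher at day 10 (log2 fold change 0.48). Because shares sum to 100%, a rise in 1 label lowers the rest.

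**Figure D1:**
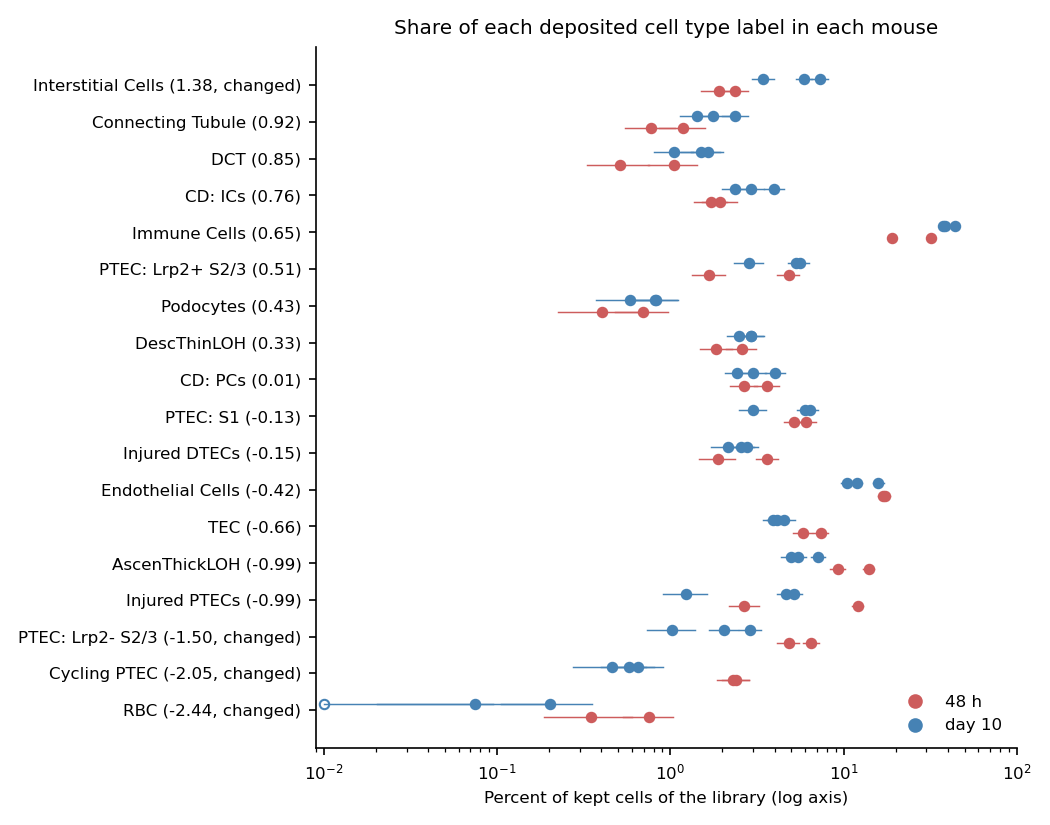
Percent of the kept cells of a library (log axis) that carry each deposited cell type label, each point 1 mouse with its exact 95% binomial interval, red for 48 h and blue for day 10. The value beside each label is the log2 fold change, with the 4 labels that passed marked as changed, and the open point at the left edge is a mouse with 0 cells of the label.

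Within the immune cells, the balance moved from neutrophils to macrophages. The deposited clustering splits the immune label into 4 clusters, and comparing these was chosen after the data were seen. Cluster 0, in which all 9 macrophage markers were detected, was 53.3% (SD 2.49) of immune cells at 48 h and 86.8% (SD 4.74) at day 10 (log2 fold change 0.70, SE 0.14, adjusted p = 0.00676). Cluster 5, with all 7 neutrophil markers, fell from 39.6% to 8.58% (log2 fold change -2.20, SE 0.35, adjusted p = 0.00479), and cluster 12, with all 6 B cell markers, from 3.06% to 0.622% (-2.26, SE 0.35, adjusted p = 0.00479). Cluster 10, with all 9 T cell markers and natural killer genes, was 4.08% and 4.02% (adjusted p = 0.997). With TMM factors over the 4 clusters none passed, and without mouse 1, 2 or 5 the share of cluster 0 did not pass. In the immune label as a whole 2774 of 14425 genes changed, 1442 up and 1332 down, among them Apoe (log2 fold change 4.20), the lysosomal glycoprotein Gpnmb (3.77), Retnlg (-5.93), S100a8 (-4.70) and the interferon-induced Slfn4 (-4.83). These sums mix the clusters, whose shares changed, and the count was 128 without mouse 2 and 580 without mouse 1.

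In the macrophage-like cluster 0, monocyte-derived macrophage genes were lower and resident macrophage genes higher at day 10. The kinds of cells differed between the times: of own subclusters of the immune cells, those named monocyte held 142, 252, 5, 7 and 1 cells and 93, 118, 26, 39 and 31 cells of mice 1 to 5. The largest subcluster named macrophage held 1, 0, 665, 11 and 341 cells. A replacement of cells and a change within cells were therefore not separated here. Of 16 monocyte-derived macrophage genes 9 fell and 0 rose, including the matrix proteoglycan Vcan (193 to 6.94 CPM, log2 fold change -4.72, SE 0.69, adjusted p = 0.00784), the monocyte surface antigen Ly6c2 (-4.20, adjusted p = 0.00808), Plac8 (-3.79, adjusted p = 0.00282), Hp (-3.35) and the calcium-binding S100a4 (-2.84). The list was called down by camera (adjusted p = 1.16e-07, adjusted p = 0.331 with an estimated correlation; 11 fell adjusted over the list alone). Of 16 resident macrophage genes 10 rose and 0 fell, led by the scavenger receptor Cd163 (log2 fold change 4.01, SE 1.06), Apoe (3.95, SE 0.16, adjusted p = 0.00124) and Ms4a7 (2.02), with the complement subunit C1qa (1.08) and the fractalkine receptor Cx3cr1 (0.65) also higher. Cd163 was 18.8, 166 and 45.15 CPM in mice 3, 4 and 5 and did not pass without mouse 1, 2 or 5, and a subcluster with Cd163 among its top genes held 412 of its 422 cells from mouse 4. The resident macrophage list had camera adjusted p = 4.37e-07 and 0.331 with an estimated correlation, and 13 rose adjusted over the list alone. Of 16 reparative macrophage genes 8 rose and 1 fell: Mmp12 (4.21) and the growth factor Igf1 (3.71) rose and the fatty acid receptor Cd36 fell (-1.04; camera adjusted p = 0.00781, 0.518 with an estimated correlation; 8 rose and 1 fell adjusted over the list alone). The chemokine receptor Ccr2 (log2 fold change -0.81, adjusted p = 0.0648), Spp1 (-0.98, adjusted p = 0.168) and the arginine-degrading enzyme Arg1 (0.35, adjusted p = 0.733) did not pass. Arg1 was 315 CPM (SD 3.58) at 48 h and 386 CPM (SD 346) at day 10, and without mouse 4 its log2 fold change was -0.71 (adjusted p = 0.0470). Ccr2 passed with the DESeq2 Wald test, without a filter on low counts and with equal numbers of cells and counts.

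S-phase and glycolysis transcripts were lower in cluster 0 at day 10 as well. All 25 S-phase genes fell, such as the replication helicase subunit Mcm2 (49.4 to 11.3 CPM, log2 fold change -2.08, SE 0.29, adjusted p = 0.00692), the methylation reader Uhrf1 (-2.16) and the cyclin Ccne2 (-2.19; camera adjusted p = 4.33e-15, 0.437 with an estimated correlation). Of 15 glycolysis genes 10 fell, including the lactate exporter Slc16a3 (-1.84), the pyruvate kinase Pkm (-1.47) and the enolase Eno1 (-1.40), and 12 when adjusted over the list alone. The glycolysis list had camera adjusted p = 1.22e-06 and 0.331 with an estimated correlation. The chemokines Ccl2 (1200 to 147 CPM, log2 fold change -2.98, SE 0.28), Ccl4 (-2.48) and Ccl7 (-2.34) and the oxysterol-producing Ch25h (-3.01) fell, while Ccl8 rose from 6.41 to 690 CPM (6.89, SE 1.05, adjusted p = 0.00879). Of 14 complement genes 9 rose and 2 fell, with C4b at 5.12 (camera adjusted p = 0.00250, 0.331 with an estimated correlation; 10 rose and 2 fell adjusted over the list alone). Of 13 iron handling genes 6 rose, including the ferroxidase Cp (5.23), the iron exporter Slc40a1 (3.39) and the iron carrier Trf (3.02), and 2 fell, among them the transferrin receptor Tfrc (-1.55). The iron handling list had camera adjusted p = 0.0449 and 0.528 with an estimated correlation, and 8 rose and 2 fell adjusted over the list alone. Of 8 genes of class II antigen presentation Ciita, the transactivator of the class (2.81, adjusted p = 0.0462), and the protease Ctss (0.92, adjusted p = 0.00898) rose, and 8 rose adjusted over the list alone. The antigen presentation list had camera adjusted p = 0.00661 and 0.528 with an estimated correlation. Class II cells were uneven between the day 10 mice. An own subcluster named macrophage, with H2-Aa and Cd74 among its top genes, held 6, 2, 363, 17 and 423 cells of mice 1 to 5. Other large changes were rises of Gpr34 (3.53), the proton pump subunit Atp6v0d2 (5.79) and Arhgap19 (3.53) and falls of S100a8 (-5.51), Wfdc21 (-5.45) and the leukotriene receptor Ltb4r1 (-2.82). S100a8 and Wfdc21 are also top genes of the neutrophils, whose share fell, and neutrophil RNA as a source of these falls was not analysed here. In cluster 0, 3364 of 13980 genes changed, 1610 up and 1754 down. Of the 37 genes named here that passed, 19 kept the call without each mouse in turn, while the count went from 181 (without mouse 2) to 4306 (without mouse 4).

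In the neutrophil-like cluster 5, neutrophil activation and interferon genes were lower at day 10 and p53 targets higher. Of own subclusters named neutrophil, one with Retnlg and S100a8 held 276, 477, 42, 13 and 37 cells of mice 1 to 5 and one with Siglecf and Csf1 held 52, 38, 184, 74 and 169, so these changes go with a shift between subclusters. Of 16 interferon response genes 10 fell and 0 rose, including Ifi27l2a (639 to 95.8 CPM, log2 fold change -3.09, SE 0.53, adjusted p = 0.00354), Xaf1 (-2.98) and the ubiquitin-like Isg15 (-2.45). The interferon response list had camera adjusted p = 3.63e-07 and 0.445 with an estimated correlation, and 13 fell adjusted over the list alone. Of 15 neutrophil activation genes 9 fell, such as the granule protein Ngp (-3.87), Retnlg (-3.18) and the iron-siderophore binder Lcn2 (-2.68), and 3 rose: the chemokine Ccl3 (15.5 to 259 CPM, 3.71, SE 0.38), the adhesion molecule Icam1 (1.56) and the sialic acid receptor Siglecf (1.26). That list was called down (camera adjusted p = 0.00594, 0.445 with an estimated correlation; 4 rose and 9 fell adjusted over the list alone). Of 11 p53 targets 5 rose and 1 fell, led by the cell cycle inhibitor Cdkn1a (10.1 to 174 CPM, 3.69, SE 0.27, adjusted p = 3.40e-05). The p53 list had camera adjusted p = 0.0138 and 0.445 with an estimated correlation, and 6 rose and 1 fell adjusted over the list alone. The leukotriene synthase Ltc4s rose (4.09, adjusted p = 8.32e-05). In cluster 5, 1202 of 6496 genes changed (506 up, 696 down), 767 with the DESeq2 Wald test, under which Ifi27l2a and Isg15 did not pass. The count was 408 with equal numbers of cells and counts and 504 without mouse 5. In the T and natural killer cells of cluster 10 only 4 of 4119 genes changed (321 had an unadjusted p under 0.05 in the edgeR test): the cytotoxic proteins Gzma (2940 to 450 CPM, log2 fold change -2.71, SE 0.19, adjusted p = 1.43e-05), Gzmb (-2.09, adjusted p = 0.00711) and Prf1 (-1.96, adjusted p = 0.00189) fell and Apoe rose (4.28, adjusted p = 0.0477). Apoe was named after its value was seen. Its 571 CPM in cluster 10 at day 10 stood against 39300 CPM in cluster 0, and macrophage RNA as its source was not analysed here. The count was 52 without mouse 4, 2 without mouse 5 and 1 with equal numbers of cells and counts, and of the 4 genes only Gzma kept the call without each mouse and under the other alternatives. The own subcluster of natural killer cells, with Gzma, Prf1 and Gzmb among its top genes, held 13, 8, 17, 5 and 15 cells and that of T cells 37, 24, 106, 30 and 79, and this shift was not separated from a change within cells.

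In the proximal tubule, cell cycle transcripts fell, 3 genes each of the failed-repair and inflammatory lists rose and 3 iron handling genes fell, while the injury genes Havcr1, Lcn2 and Krt20 did not pass. Of 25 S-phase genes 24 fell and 0 rose, including the licensing factor Cdc6 (5.39 to 0.600 CPM, log2 fold change -3.40, SE 0.34, adjusted p = 0.0112), Cdc45 (-3.09), the chromatin remodeller Hells (-3.00, SE 0.19, adjusted p = 0.00346) and the replication clamp Pcna (-1.89). The S-phase list had camera adjusted p = 4.43e-32 and 0.355 with an estimated correlation, and 25 fell adjusted over the list alone. Cells labelled cycling were 9.90% of proximal tubule cells at 48 h and 3.88% at day 10. Without the cells labelled cycling or injured, the count of changed proximal tubule genes stayed within 1.5 times of that over all its cells. The cell cycle lists were not tested in that set. For these lists the shift was therefore not separated from a change within cells. Of 25 G2/M genes 13 fell, such as the kinase Aurkb (-2.18), the spindle motor Kif11 (-2.16), the proliferation marker Mki67 (-2.14) and the topoisomerase Top2a (-2.06; camera adjusted p = 6.25e-17, 0.355 with an estimated correlation; 24 fell adjusted over the list alone). Of 17 failed-repair markers 3 rose, the chemokine Ccl2 (2.66 to 74.4 CPM, 4.58, SE 0.24, adjusted p = 0.00246), the class II chaperone Cd74 (3.38, adjusted p = 0.0284) and the kinase Tnik (3 UMIs at 48 h and 106 at day 10, 23.02 times as high, 95% interval 7.665 to 113.4), and 6 adjusted over the list alone. The failed-repair list had camera adjusted p = 2.52e-08 and 0.355 with an estimated correlation. Vcam1, an adhesion molecule of that list, was 14.0 CPM (SD 14.5) at 48 h and 141 CPM (SD 57.1) at day 10 (log2 fold change 3.04, adjusted p = 0.0860), and it passed with the DESeq2 Wald test and without a filter on low counts. Of 25 injury markers only the hyaluronan receptor Cd44 rose (2.94 to 30.3 CPM, 3.12, SE 0.17, adjusted p = 0.00246). The injury list had camera adjusted p = 0.00815 and 0.590 with an estimated correlation, and 4 rose adjusted over the list alone. Its direction turned without mouse 2 (adjusted p = 0.781). Havcr1, the kidney injury molecule, was 343 CPM (SD 378) and 219 CPM (SD 99.0), with a log2 fold change of -0.91 (adjusted p = 0.515) that was 1.31 without mouse 1. Lcn2 (0.41, adjusted p = 0.640), Krt20 (0.71, adjusted p = 0.371), Spp1 (-1.30, adjusted p = 0.217), the phosphate transporter Slc34a1 (0.01, adjusted p = 0.993) and the endocytic receptor Lrp2 (-0.70, adjusted p = 0.134) did not pass. Among proximal tubule cells with no state label Krt20 fell (-1.93, adjusted p = 0.0401) and the value of Lcn2 was -0.83.

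Fatty acid oxidation genes of the proximal tubule fell as well. The mix of proximal tubule cells differed between the times. The Lrp2-negative S2/3 label went from 23.3% of them at 48 h to 12.3% at day 10. The Lrp2-positive S2/3 label went from 14.7% to 29.6% and the S1 label from 24.0% to 32.7%. Acaa1b was a top gene of an own cluster whose most frequent label was Lrp2-negative S2/3. This shift was not separated from a change within cells. Of 27 fatty acid oxidation genes 6 fell and 0 rose, including the fatty acid hydroxylase Cyp4a10 (234 to 98.8 CPM, log2 fold change -1.51, SE 0.17, adjusted p = 0.0124) and the thiolase Acaa1b (-1.29). The fatty acid oxidation list had camera adjusted p = 3.59e-08 and 0.355 with an estimated correlation, and 12 fell adjusted over the list alone. Cyp4a12a (-1.71), Cyp4a12b (-1.70) and Cd36 (-2.08), which handle fatty acids, fell too. Of 13 iron handling genes 3 fell, among them Tfrc (-2.44, SE 0.29, adjusted p = 0.0151) and the ferritin heavy chain Fth1 (33200 to 9470 CPM, -2.07, SE 0.23, adjusted p = 0.0121). The iron handling list had camera adjusted p = 0.00815 and 0.355 with an estimated correlation, and 1 rose and 5 fell adjusted over the list alone. The calcium-binding S100g fell from 1150 to 131 CPM (-3.40, SE 0.29, adjusted p = 0.00808). Of 30 differentiated proximal tubule genes only the protease Napsa rose (2.01, adjusted p = 0.0319; camera adjusted p = 0.184; 2 rose and 3 fell adjusted over the list alone). The peptidase Mme (1.78), the glypican Gpc3 (2.49), the sulfurtransferase Tstd1 (1.32), the integrin Itga1 (0.81), Cited2 (0.79) and the desaturases Scd1 (3.81) and Scd2 (3.13) also rose, and the kinetochore component Spc25 fell (-2.19). Of 21 inflammatory cytokine and NF-kB genes 3 rose, including the feedback inhibitor Tnfaip3 (1.88). The inflammatory cytokine and NF-kB list had camera adjusted p = 1.54e-05 and 0.355 with an estimated correlation, and 4 rose adjusted over the list alone. In the proximal tubule 447 of 13899 genes changed, 178 up and 269 down. The count was 59 with equal numbers of cells and counts per library and between 27 (without mouse 5) and 594 (without mouse 1) with a mouse left out. Of the 36 named genes that passed, Ccl2, Cd44, Hells and S100g did so without each mouse in turn and 5 did so under all other alternatives.

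Macrophage transcripts rose in the proximal tubule beside these changes. Of 15 resident macrophage genes 8 rose and 0 fell, such as C1qa (4.57 to 47.2 CPM, log2 fold change 3.06, SE 0.39, adjusted p = 0.0166), C1qc (3.05) and C1qb (2.66). The resident macrophage list had camera adjusted p = 6.70e-08 and 0.355 with an estimated correlation, and 10 rose adjusted over the list alone. Of 8 class II antigen presentation genes 4 rose, with H2-Aa at 3.41, Cd74 at 3.38 and H2-Eb1 at 2.72 (camera adjusted p = 3.87e-06, 0.355 with an estimated correlation; 7 rose adjusted over the list alone). The same resident macrophage list was called up in the thick ascending limb, where 11 of 13 genes rose (camera adjusted p = 5.02e-12, 0.311 with an estimated correlation; 12 rose adjusted over the list alone), with C1qa at 4.16 and C1qc at 4.76. In the distal tubule and principal cells 0 of 13 passed over all genes and 10 rose adjusted over the list alone (camera adjusted p = 7.58e-13, 0.283 with an estimated correlation). In the TEC-labelled tubule 5 of 12 rose (camera adjusted p = 9.43e-13, 0.203 with an estimated correlation; 11 rose adjusted over the list alone). In immune cluster 0 the level of C1qa was 4750 CPM at day 10, so the 47.2 CPM of the proximal tubule were a small fraction of it. Leaving out genes whose level in the proximal tubule was under 0.2 times that in the rest of the cells reduced the proximal tubule count from 447 to 291, of which 70 rose and 221 fell.

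In the thick ascending limb, the sodium-reabsorbing segment, mitochondrial, endoplasmic reticulum stress and segment identity transcripts fell, and proximal tubule failed-repair markers rose. All 13 mitochondrially encoded genes fell, with a median log2 fold change of -1.85, led by mt-Nd4l (-2.44), mt-Nd4 (14600 to 3610 CPM, -2.37, SE 0.14, adjusted p = 0.000530) and mt-Nd2 (-2.31), all subunits of respiratory complex I (camera adjusted p = 4.75e-18, 0.311 with an estimated correlation). Of 17 endoplasmic reticulum and integrated stress genes 10 fell, including the chaperones Sdf2l1 (-2.27), Hspa5 (1220 to 413 CPM, -1.92, SE 0.42, adjusted p = 0.0323) and the secreted Creld2 (-1.56; camera adjusted p = 3.35e-08, 0.340 with an estimated correlation; 15 fell adjusted over the list alone), and the chaperone Hyou1 fell too (-1.84). Of 13 identity genes 6 fell, among them Slc5a3 (1100 to 404 CPM, -1.81, SE 0.13, adjusted p = 0.00108), Wfdc15b (-1.45), Ppp1r1a (-1.33) and Umod (13300 to 9000 CPM, -0.92, SE 0.21, adjusted p = 0.0346), and the paracellular magnesium channel Cldn16 rose (0.97). The identity list had camera adjusted p = 0.0166 and 0.552 with an estimated correlation, and 1 rose and 6 fell adjusted over the list alone. Of 26 fatty acid oxidation genes 7 fell, including the glucose oxidation brake Pdk4 (-3.13), Acadvl (-1.15) and Cpt2 (-1.11). The fatty acid oxidation list had camera adjusted p = 8.35e-06 and 0.405 with an estimated correlation, and 2 rose and 16 fell adjusted over the list alone. Of 43 nuclear oxidative phosphorylation genes 5 fell and 0 rose, with a median of only -0.22 (camera adjusted p = 3.87e-05, 0.552 with an estimated correlation; 8 fell adjusted over the list alone). Among iron handling genes Tfrc (95.2 to 15.4 CPM, -2.98, SE 0.20, adjusted p = 0.000929) and Fth1 (-1.74) fell and Cp rose (3.14; 2 rose and 3 fell of 13; camera adjusted p = 0.0162, 0.329 with an estimated correlation; 2 rose and 6 fell adjusted over the list alone).

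**Figure D2:**
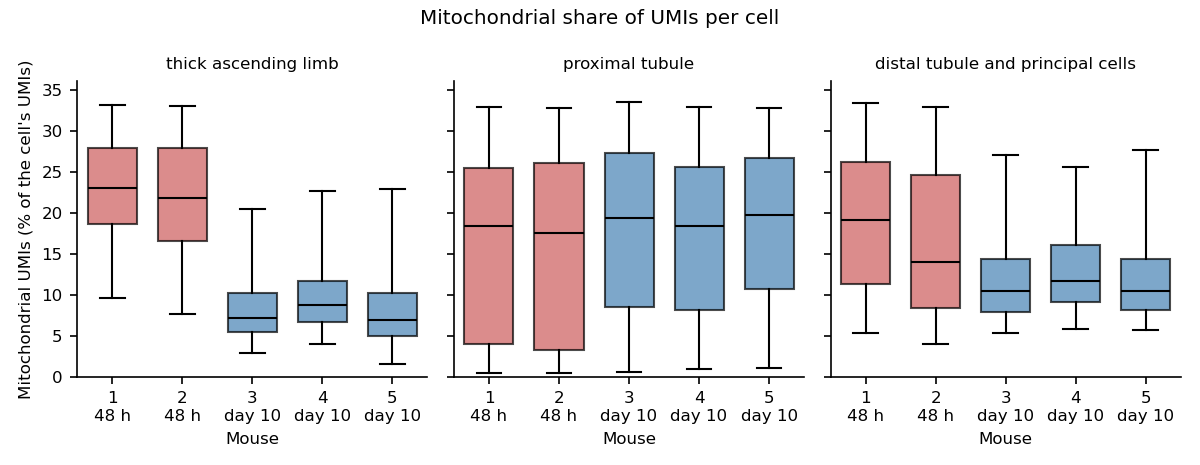
Mitochondrial UMIs in percent of each cell's UMIs by mouse, in thick ascending limb, proximal tubule and distal tubule and principal cells. Lines are medians, boxes the middle 50% of cells and whiskers the 5th to 95th percentile; the thick ascending limb medians were 22.97 and 21.82% at 48 h and 7.20, 8.70 and 6.89% at day 10.

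The rising genes of the thick ascending limb included members of the proximal tubule injury and failed-repair lists. Of 24 injury markers 4 rose, such as the keratins Krt19 (5.34 to 121 CPM, log2 fold change 4.19, SE 0.32, adjusted p = 0.00114), Krt20 (2.94) and Krt18 (1.92), and 2 fell, the secreted chaperone Clu (-1.67) and the matrix phosphoprotein Spp1 (78300 to 38200 CPM, -1.39). The injury list had camera adjusted p = 0.0499 and 0.631 with an estimated correlation, and 5 rose and 2 fell adjusted over the list alone. Without mouse 2 its direction turned (adjusted p = 0.687). Of 17 failed-repair markers 5 rose, including the scaffold Akap12 (3.61), Vcam1 (0.802 to 11.3 CPM, 3.27, SE 0.53, adjusted p = 0.0136) and Cp. The failed-repair list had camera adjusted p = 0.00218 and 0.456 with an estimated correlation, and 7 rose adjusted over the list alone. Cp also rose in immune cluster 0, and resident macrophage genes rose in the thick ascending limb. RNA of other cells as a source of these failed-repair rises was not analysed here. Of 15 p53 targets Phlda3 (2.79), Plk2 (2.00) and the apoptosis activator Bbc3 (0.93) rose, but the list did not pass (camera adjusted p = 0.148; 5 rose and 2 fell adjusted over the list alone). The surface protein Psca (6.24), the protease Mmp7 (3.60), the matrix protein Fn1 (3.49), S100a6 (218 to 2610 CPM, 3.21), the steroid reductase Srd5a1 (3.19), the transcription regulators Id3 (2.83) and Scx (2.17), Tmem52b (2.57), Tmem158 (2.09) and the hexokinase Hk2 (1.88) rose. The lipase inhibitor Angptl4 (-2.21), the branched-chain dehydrogenase subunit Bckdhb (-2.16), the NAD-producing Nampt (-2.00), the sodium-proton exchanger Slc9a3 (-1.95) and Pkm (-0.64) fell. In the thick ascending limb 1325 of 12797 genes changed, 637 up and 688 down, and 57.4% of tested genes did not overlap between the groups (chance share 20%). The count was 86 without mouse 5 and 2429 without a filter on low counts, and 16 of the 46 named genes that passed did so without each mouse in turn. With own clusters in place of the deposited labels 882 genes changed and Krt19, Akap12, Psca, Wfdc15b, Plk2 and Stmn1 did not pass.

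**Figure D3:**
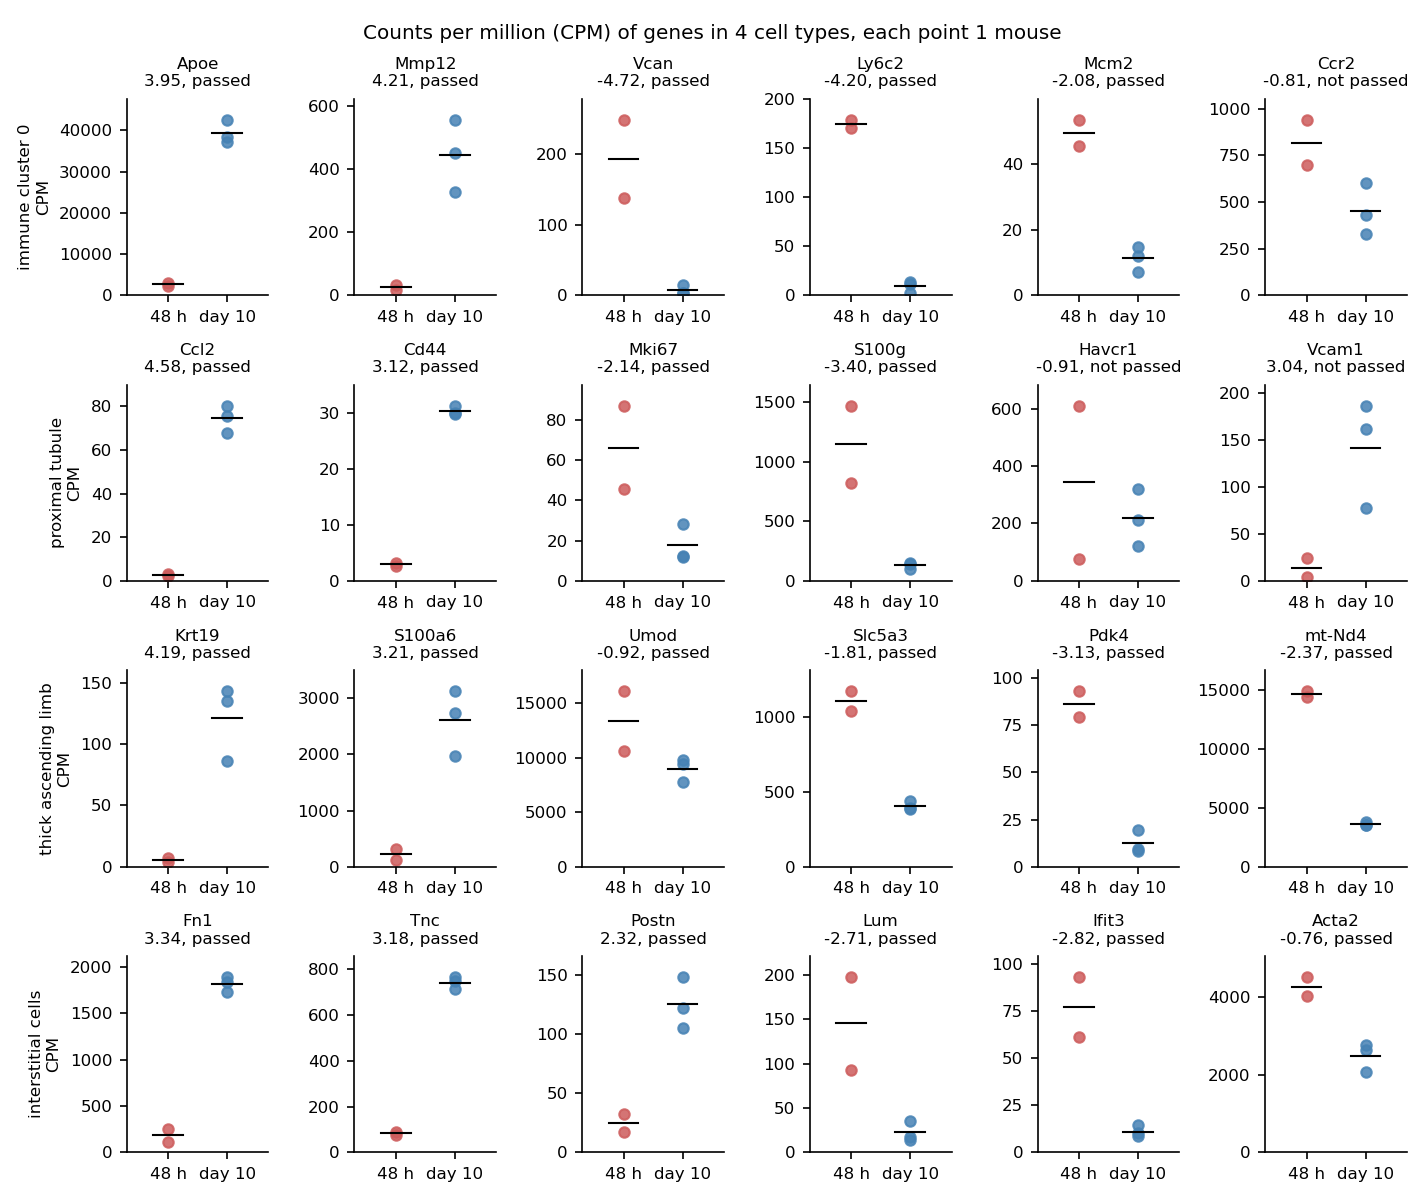
CPM of summed UMIs (linear axes from 0) of 6 genes in each of 4 cell types, each point 1 mouse, red for 48 h and blue for day 10, with a black line at the group mean. Below each gene stand its log2 fold change and whether it passed; Havcr1 and Vcam1 in the proximal tubule and Ccr2 in immune cluster 0 did not.

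The time effect differed between the proximal tubule and the thick ascending limb for 1038 of 14063 genes in the interaction test with mouse as a block, 515 with the change in the thick ascending limb above that in the proximal tubule and 523 below. Of 103 genes that changed in both segments 97 moved the same way, and 6 differed and moved in opposite directions. Stmn1, a microtubule-destabilizing protein counted among the G2/M genes, fell in the proximal tubule (log2 fold change -1.04, adjusted p = 0.0298) and rose in the thick ascending limb (20.8 to 61.0 CPM, 1.17, adjusted p = 0.0402), a difference of 2.23 (SE 0.31, adjusted p = 0.00809). It was the only gene of the 6 that met the rule for named genes. The rise of Stmn1 in the thick ascending limb did not pass with own clusters, nor in every fit with a mouse left out. Cells labelled cycling were 9.90% of proximal tubule cells at 48 h and 3.88% at day 10. The number of differing genes was 137 without mouse 5, 293 without mouse 3 and 1668 without a filter on low counts.

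In endothelial cells interferon response genes fell. The mix of cells differed between the times: of own clusters, one with Plvap, Fabp4 and Rsad2 held 579, 425, 428, 387 and 262 cells of mice 1 to 5, one with Ehd3 and Kdr 106, 57, 126, 82 and 123, and one with Sox17 66, 83, 116, 89 and 121. This shift and changes within cells were not separated here. Of 22 interferon response genes 4 fell and 0 rose, including the antiviral Ifit3 (181 to 59.6 CPM, log2 fold change -1.69, SE 0.17, adjusted p = 0.0297), the transcription factor Irf7 (-1.54) and Ifit2 (-1.37), and 19 fell adjusted over the list alone. The interferon response list had camera adjusted p = 1.66e-21 and 0.322 with an estimated correlation. Of 12 class I antigen presentation genes H2-T23 fell (-0.92, adjusted p = 0.0373), and 11 fell adjusted over the list alone. The class I antigen presentation list had camera adjusted p = 1.39e-12 and 0.322 with an estimated correlation. The fatty acid receptor Cd36 (231 to 39.0 CPM, -2.66, SE 0.24, adjusted p = 0.0297) and the fatty acid binding protein Fabp4 (6510 to 2530 CPM, -1.45) fell, as did the transcription factor Tcf15 (-1.39), Car8 (-1.44), the glutathione transferase Gstm1 (-1.14), Flrt3 (-1.15) and Khdrbs3 (-1.23). The clotting factor carrier Vwf rose from 32.0 to 94.5 CPM (1.49, SE 0.22, adjusted p = 0.0482), with the membrane protease Mmp14 (1.37), the myosin Myh10 (1.17), Kbtbd11 (1.10) and Arl4a (0.95). Of 18 cholesterol and lipid synthesis genes 0 passed over all genes and 10 rose adjusted over the list alone (camera adjusted p = 3.46e-08, 0.322 with an estimated correlation). The activation list did not pass (camera adjusted p = 0.560; 1 rose and 3 fell adjusted over the list alone): Vcam1 (-0.76, adjusted p = 0.0804), Plvap (-0.77, adjusted p = 0.151) and the VEGF receptor Kdr (0.17, adjusted p = 0.565) stayed above the threshold, although Vcam1 and Plvap passed with the DESeq2 Wald test. In endothelial cells 40 of 12190 genes changed (15 up, 25 down; 1698 had an unadjusted p under 0.05), 211 with the DESeq2 Wald test. The count was 0 without mouse 1, 2 or 5.

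The distal tubule and principal cells showed a single changed gene of 12915 in the edgeR test, with 1023 at an unadjusted p under 0.05. This was Krt15, a keratin of urothelium and basal cells named after its value was seen, with 499 UMIs at 48 h and 1 at day 10, 961 times as high at 48 h (95% interval 172 to 38030, adjusted p = 0.00145). Krt15 did not pass without mouse 5. Of 13 mitochondrially encoded genes 0 passed over all genes and 13 fell adjusted over the list alone (median log2 fold change -0.80, camera adjusted p = 7.67e-20, 0.283 with an estimated correlation). Of 7 class II antigen presentation genes 0 passed and 6 rose adjusted over the list alone (camera adjusted p = 1.11e-05, 0.283 with an estimated correlation). The count of genes was 0 without mouse 5, 12 without mouse 2 and 92 without a filter on low counts.

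The TEC label is not spelled out in the sources used here; its 1210 cells had a low depth, and 961 of them fell into own clusters named thick ascending limb by fixed markers. In these cells the lists of thick ascending limb identity and fatty acid oxidation went down and those of proximal tubule failed-repair markers and p53 targets up. Of 11 identity genes 4 fell, among them the sodium-potassium-chloride transporter Slc12a1 (343 to 62.6 CPM, log2 fold change -2.57, SE 0.25, adjusted p = 0.000965), Umod (-2.16) and Wfdc15b (-2.07). The identity list had camera adjusted p = 1.45e-13 and 0.141 with an estimated correlation, and 10 fell adjusted over the list alone. Of 15 failed-repair markers Vcam1 rose (5.34 to 86.2 CPM, 3.91, SE 0.55, adjusted p = 0.00918). The failed-repair list had camera adjusted p = 4.77e-05 and 0.202 with an estimated correlation, and 5 rose adjusted over the list alone. Of 14 p53 targets Pmaip1 (2.61) and Plk2 (1.92) rose, with 3 adjusted over the list alone. The p53 list had camera adjusted p = 1.07e-06 and 0.203 with an estimated correlation. Of 24 fatty acid oxidation genes only Pdk4 fell over all genes (-3.00), and 10 adjusted over the list alone. The fatty acid oxidation list had camera adjusted p = 1.09e-12 and 0.202 with an estimated correlation. The membrane-associated Basp1 (8.83 to 177 CPM, 4.24, SE 0.38, adjusted p = 0.000798), the claudins Cldn3 (3.04) and Cldn4 (2.07), the collagen chain Col4a2 (2.63), Bok (2.53) and Scx (1.94) rose, and Hesx1 (-3.35), Eprn (-2.29), Ly6d (-4.40) and the globin Hba-a1 (-6.84, SE 1.25) fell, although Ly6d and Hba-a1 did not pass with the DESeq2 Wald test. Hba-a1 was 2785 CPM in mouse 1, 57.1 CPM in mouse 2 and 12.6 CPM at day 10, and it did not pass without mouse 1. In all 41 of 7809 genes changed (22 up, 19 down), 1 without mouse 5 and 93 without mouse 2.

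In the descending thin limb, p53 targets and genes of the proximal tubule failed-repair and injury lists rose. The cell cycle inhibitor Cdkn2a had 0 UMIs at 48 h and 471 at day 10, at least 52.8 times as high against a floor of 3 counts (adjusted p = 0.000414). Of 15 p53 targets 8 rose and 0 fell, including the apoptosis activators Pmaip1 (1.44 to 40.7 CPM, log2 fold change 4.57, SE 0.64, adjusted p = 0.00539) and Bbc3 (1.96) and Phlda3 (2.51). The p53 list had camera adjusted p = 2.24e-08 and 0.150 with an estimated correlation, and 11 rose and 1 fell adjusted over the list alone. Of 17 failed-repair markers 6 rose, among them Ccl2 (6.28 to 144 CPM, 4.43), Vcam1 (46.8 to 290 CPM, 2.58, SE 0.27, adjusted p = 0.00152) and the growth factor Pdgfb (1.97). The failed-repair list had camera adjusted p = 1.05e-07 and 0.150 with an estimated correlation, and 13 rose and 1 fell adjusted over the list alone. Of 24 injury markers 6 rose, including Krt19 (2.61), the transcription factor Sox9 (2.46) and Cd44 (2.16). The injury list had camera adjusted p = 4.70e-05 and 0.530 with an estimated correlation, and 8 rose and 1 fell adjusted over the list alone. Basp1 (4.26) and Fn1 (2.78) rose, and the water channel Aqp1 (1210 to 364 CPM, -1.77, SE 0.39, adjusted p = 0.0350) and the vessel destabilizer Angpt2 (151 to 24.8 CPM, -2.64) fell. Of 43 nuclear oxidative phosphorylation genes 8 fell (camera adjusted p = 2.47e-14, 0.209 with an estimated correlation; 19 fell adjusted over the list alone). Genes of the neighbouring thick ascending limb fell too, 7 of 11 over all genes and 10 adjusted over the list alone. That list had camera adjusted p = 1.43e-10 and 0.209 with an estimated correlation. Umod was at -2.59 and did not pass with own clusters. The thick ascending limb label went from 11.6% of cells at 48 h to 5.85% at day 10. Its RNA as a source of these falls was not analysed here. In this segment 573 of 11192 genes changed, 310 up and 263 down, and 163 without mouse 2; Aqp1 and Pdgfb did not pass with the DESeq2 Wald test. In intercalated cells, the acid-base cells of the collecting duct, 25 of 10510 genes changed (7 up, 18 down; 0 without mouse 5): Basp1 (5.61 to 44.6 CPM, 2.90), the matrix proteoglycan Dcn (3.92) and the signalling regulator Rgs2 (1.34) rose, and the cyclin Ccnd1 (108 to 25.6 CPM, -2.22, SE 0.20, adjusted p = 0.0113), the sodium pump regulator Fxyd4 (-2.13) and the small heat shock protein Cryab (1020 to 337 CPM, -1.72) fell. Dcn is among the fixed fibroblast markers, and the share of interstitial cells rose. Fxyd4 is among the fixed principal cell markers. RNA of those cells as a source of these 2 changes was not analysed here.

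In the interstitial cells, extracellular matrix and sterol synthesis genes rose and interferon response genes fell. The mix of cells under the label differed between the times: of own clusters, one with Col1a1 and Col3a1 held 21, 21, 242, 213 and 98 cells of mice 1 to 5, one with Myh11 and Acta2 30, 20, 67, 56 and 47, and one with Itga8 56, 28, 43, 26 and 40. Changes of this mix and changes within cells were not separated here. Of 25 extracellular matrix genes 15 rose, among them Fn1 (183 to 1820 CPM, log2 fold change 3.34, SE 0.34, adjusted p = 0.00163), Tnc (83.6 to 741 CPM, 3.18, SE 0.17, adjusted p = 0.000339), Thbs1 (2.96) and Postn (24.9 to 125 CPM, 2.32), and the collagen-binding Lum fell (-2.71, SE 0.42, adjusted p = 0.00781). The extracellular matrix list had camera adjusted p = 2.48e-12 and 0.243 with an estimated correlation, and 17 rose and 2 fell adjusted over the list alone. The collagen chain Col1a1 was 1780 CPM (SD 657) and 2530 CPM (SD 292), which did not pass (0.53, adjusted p = 0.213). Of 14 myofibroblast activation genes 3 rose, including the protease Fap (2 UMIs at 48 h and 223 at day 10, 15.7 times as high, 95% interval 4.29 to 130) and the cytokine Tgfb1 (1.24), and 4 fell, the contractile Cnn1 (-1.61), Tpm2 (-0.96), Myl9 (-0.79) and the smooth muscle actin Acta2 (4250 to 2490 CPM, -0.76, SE 0.14, adjusted p = 0.0173). The list did not pass (camera adjusted p = 0.994; median log2 fold change 0.16; 4 rose and 5 fell adjusted over the list alone), and without the cells with the highest doublet scores the value of Acta2 was 0.23 (adjusted p = 0.939) and Cnn1, Tpm2, Myl9, Lum and Tgfb1 did not pass. Of 20 interferon response genes 11 fell and 0 rose, such as Ifit3 (77.1 to 11.1 CPM, -2.82, SE 0.28), Usp18 (-2.78) and Ifit1 (-2.59). The interferon response list had camera adjusted p = 1.96e-12 and 0.243 with an estimated correlation, and 15 fell adjusted over the list alone. Of 17 cholesterol and lipid synthesis genes 8 rose, including Idi1 (1.89) and Insig1 (1.79). The cholesterol and lipid synthesis list had camera adjusted p = 4.38e-07 and 0.243 with an estimated correlation, and 11 rose adjusted over the list alone. The collagen Col10a1 had 0 UMIs at 48 h and 930 at day 10 (at least 43.6 times as high against a floor of 3 counts), and the signalling regulator Nkd2 (1 UMI at 48 h and 1387 at day 10, 195 times as high, 95% interval 34.9 to 7701) and the transcription factor Tfap2a (1 and 542 UMIs, 76.1 times, 13.6 to 3013) rose. The chemokine Pf4 (-3.56), the gap junction protein Gja5 (-3.20) and Nrgn (-3.10) fell, and so did the endothelial genes Cd34 (149 to 28.2 CPM, -2.38), Plvap (135 to 33.8 CPM, -1.98) and Angpt2 (-1.36), which did not pass with own clusters. In interstitial cells 847 of 11392 genes changed, 445 up and 402 down; the count was 211 without mouse 1, 420 with own clusters and 471 with equal numbers of cells and counts.

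Hemoglobin transcripts, which mark red blood cells, were lower at day 10 in the immune cells and, as a list, in endothelial cells, and single hemoglobin genes also passed in the descending thin limb, the TEC-labelled tubule and immune cluster 5. Of 5 erythroid genes 3 fell in the immune cells over all genes tested and 5 adjusted over the list alone, with a median log2 fold change of -5.56 (camera adjusted p = 0.000304, 0.448 with an estimated correlation). The median was -2.88 in endothelial cells, where 0 of the 5 passed (camera adjusted p = 6.73e-05, 0.381 with an estimated correlation), and -1.87 in the proximal tubule (camera adjusted p = 0.115). The list of 10 proximal tubule transcripts, which are common in free RNA of the kidney, was called in interstitial cells, with a median of -0.55 (camera adjusted p = 0.00836, 0.641 with an estimated correlation; 1 fell adjusted over the list alone), and passed in none of the other 8 types.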

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

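The tests of free RNA as the source of resident macrophage genes, of Ccl2 and of class II genes in the proximal tubule, and the tests of free mitochondrial RNA and of the amount of other RNA in the thick ascending limb, were chosen only after the result was seen.

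A difference between groups singled out 2 results: in a test of the difference itself, the time effect differed between the proximal tubule and the thick ascending limb for 1038 genes, and for Stmn1 by a log2 of 2.23. A signal in data that the comparisons do not use singled out the barcodes with at least 35% mitochondrial UMIs, which were 28.3, 25.8, 22.0, 14.4 and 22.6% of the barcodes of mice 1 to 5. Of the UMIs outside mitochondrial genes, the list of 10 proximal tubule genes made up 2.42, 3.48, 7.37, 4.24 and 5.49% in these barcodes. The list made up 0.444, 0.462, 0.312, 0.171 and 0.301% in the kept cells outside the proximal tubule and 3.66, 4.97, 5.52, 3.87 and 5.20% in the kept proximal tubule cells. With 2 and 3 mice, no group was large enough for a test of a single distant sample.

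Macrophage transcripts were higher in the proximal tubule at day 10, and droplets that hold a macrophage and a tubule cell may explain a part: 62.8% of the C1qa, C1qb and C1qc UMIs of day 10 proximal tubule cells lay in the 44 of 2552 cells with 10 or more of them. Without the cells with the highest doublet scores the log2 fold change of C1qa was 1.98 in place of 3.06 and still passed. Free macrophage RNA cannot be told apart from tubule expression for the resident macrophage list, since 54.0% of these cells held at least 1 C1q UMI but only 50, 66.7 and 60% of the list's other genes in mice 3, 4 and 5 lay within 2-fold of the C1q ratio of the proximal tubule to immune cluster 0. Free RNA does not explain Ccl2, which was at least 24.5 times as high as the C1q-based share of the highest other cell type, and cannot be told apart for Cd74, H2-Aa and H2-Eb1, where the ratio was 6.25, 3.65 and 2.79 for Cd74 in mice 3 to 5 but as low as 1.75 for H2-Aa, and where C1q does not measure the RNA of B and dendritic cells. A change of the tubule cells themselves with time stays open as untested.

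The mitochondrial share of UMIs was lower in the thick ascending limb at day 10, by 14.8 points of the median cell. The tables argue against free mitochondrial RNA of the library (the median of immune, endothelial and proximal tubule cells rose, by at least 0.301 points, though the proximal tubule is held below 35% by the authors' limit), and against that limit itself (the median log2 fold change of the 13 genes was -1.535 with a limit of 25% and at least 500 genes). They also argue against cells of another depth (the difference was -14.35 points among cells with 10000 to 20000 UMIs) and against less of the other RNA per cell at 48 h (other UMIs per cell were 0.979 times as many at day 10, mitochondrial UMIs 0.284 times). Other types fell too: the distal tubule and principal cells by 5.73 points, the TEC-labelled tubule by 1.37, the descending thin limb by 1.20, interstitial cells by 1.18 and intercalated cells by 1.08. The labels name no batch. What stays open, all untested, includes a difference in handling that acts on these segments more than on other cells. It also includes a loss of mitochondrial RNA from these cells with time and a change in which cells of the segment were captured. The share of the thick ascending limb label went from 11.6% of cells at 48 h to 5.85% at day 10.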

How the results depend on the processing

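The tests without the cells with the highest doublet scores, without mitochondrially encoded genes and on merged subtypes and the tests of the deposited immune clusters were chosen only after the result was seen. Apart from leaving out mice, 2251 values of named genes kept direction and side of the threshold, 117 no longer passed, 13 newly passed and 8 reversed; for shares these numbers were 90, 12, 5 and 7, and for named lists 29 were the same and 83 no longer passed. Of the counts of changed genes, lists and labels 95 stayed within 1.5 times and 65 moved. With a mouse left out, 835 values of named genes were the same, 428 no longer passed, 6 newly passed and 6 reversed, and 95 counts were the same and 50 moved. Of 240 named genes past the threshold 79 kept the call without each mouse in turn and 164 under all other alternatives. No paired analysis was possible because the 48 h and day 10 mice are different animals and share no replicate numbers. Without mouse 1 or 2 the lone 48 h mouse is assumed to vary like the day 10 mice.

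Counts of changed genes with the DESeq2 Wald test were 1915 in all cells, 211 in endothelial cells, 1203 in the proximal tubule, 1.1e+02 in the distal tubule and principal cells, 62 in the TEC-labelled tubule, 84 in intercalated cells, 7 in immune cluster 10 and 767 in cluster 5. Without a filter on low counts they were 687 in all cells, 451 in endothelial cells, 1143 in the proximal tubule, 92 in the distal tubule and principal cells, 2429 in the thick ascending limb, 318 in the TEC-labelled tubule, 1306 in the descending thin limb, 408 in intercalated cells, 1705 in interstitial cells, 107 in cluster 10 and 1668 for the difference between the segments. With cell types at equal weights and limma trend the count was 642 in all cells. With own clusters it was 68 in endothelial cells, 284 in the proximal tubule, 6 in the distal tubule and principal cells, 882 in the thick ascending limb and 420 in interstitial cells. With equal numbers of cells and counts, which leave fewer cells, it was 59 in the proximal tubule, 2 in the distal tubule and principal cells, 5 in intercalated cells, 471 in interstitial cells, 1 in cluster 10 and 408 in cluster 5. Without genes under 0.2 times the rest, a setting with fewer genes, it was 291 in the proximal tubule and 23 in the TEC-labelled tubule, without the cells with the highest doublet scores 108 in endothelial cells, and without state labels 6 in the distal tubule and principal cells. Of the labels, 1 changed in share with TMM factors, with limma on logit-transformed shares and without the cells with the highest doublet scores, and 0 immune clusters did with TMM factors.

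With a correlation estimated per list 0 lists passed in each of the 13 sets of cells. With fry the counts were 2 in all cells, 12 in immune cells, 0 in endothelial cells, 7 in the proximal tubule, 1 in the distal tubule and principal cells, 8 in the thick ascending limb, 0 in the TEC-labelled tubule, 7 in the descending thin limb, 0 in intercalated cells, 0 in interstitial cells, 11 in cluster 0, 0 in cluster 10 and 5 in cluster 5.

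Leaving out each mouse in turn gave counts of changed genes from 0 to 436 in all cells, 128 to 3719 in immune cells, 0 to 60 in endothelial cells, 27 to 594 in the proximal tubule, 0 to 12 in the distal tubule and principal cells, 86 to 1379 in the thick ascending limb, 1 to 93 in the TEC-labelled tubule, 163 to 592 in the descending thin limb, 0 to 23 in intercalated cells and 211 to 702 in interstitial cells. They went from 181 to 4306 in cluster 0, 2 to 52 in cluster 10, 504 to 1214 in cluster 5 and 137 to 1220 for the difference between the segments. Lists in intercalated cells went from 8 to 20 and labels changed in share from 1 to 5.

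Values that reversed were mostly of results that had not passed. Log2 fold changes of Slc34a1 in the proximal tubule were -0.00581 with the DESeq2 Wald test, -0.00574 with DESeq2 size factors and -0.111 with at least 500 genes and at most 25% mitochondrial UMIs per cell; of Lcn2 there -0.190 with own clusters and -0.834 without state labels, where Krt20 was -1.93. Col1a1 was -0.183 in interstitial cells with own clusters and Acta2 0.234 without the cells with the highest doublet scores. With a mouse left out Havcr1 went from -1.75 to 1.31, Lcn2 from -0.106 to 1.23 and Slc34a1 from -0.454 to 0.672 in the proximal tubule, and Arg1 from -0.711 to 0.760 in cluster 0. The share of principal cells was -0.119 with TMM factors, -0.00375 with limma on logit-transformed shares and -0.131 with these 2 limits, and from -0.205 to 0.247 with a mouse left out. Injured distal cells were 0.527 with these 2 limits, 0.291 of their compartment and from -0.542 to 0.408, injured proximal tubule cells from -1.70 to 0.478, the Lrp2-positive S2/3 label from -0.0634 to 1.46, the S1 label 0.204 of its compartment and from -0.323 to 0.143, and cluster 10 of the immune cells 0.574 with TMM factors and from -0.462 to 0.634. Lists whose direction turned without a mouse had adjusted p from 0.0736 to 0.861 (endothelial activation), 4.13e-08 to 0.781 (injury markers) and 0.000293 to 0.451 (differentiated genes) in the proximal tubule, 2.79e-05 to 0.687 (injury markers in the thick ascending limb) and 0.792 to 0.987 (myofibroblast activation). Except where fewer cells, genes or mice explain a lower count, the cause was not tested.

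Own clusters gave no value for the TEC label and the immune clusters, and compartment totals none for the immune and red blood cell labels, which are compartments of their own. Doublet and cell filter alternatives were not run for the shares of the immune clusters, and cells without a state label exist as a separate set only in the proximal tubule and the distal tubule and principal cells. Depth limits the smaller sets of cells: in the TEC-labelled tubule 19% of simulated 2-fold changes were recovered, and immune clusters 5 and 10, whose smallest libraries had fewer UMIs, were not simulated.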

Other observations

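Both tests in this part were written before their results were seen, the comparison between other mice was added after, and the hypothesis came from genes whose values had been seen: Fkbp5 (22.3, 48.1, 27.2, 126 and 28.0 CPM in mice 1 to 5, all cells summed), Zbtb16, Per1, Tsc22d3 and Sgk1, with a median log2 ratio of mouse 4 to the mean of mice 3 and 5 of 1.43.

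A glucocorticoid response of mouse 4 cannot be told apart from ordinary variation between mice, since it rests on 1 mouse and random lists do not measure that variation: between mice 1 and 2 the same list lay outside 5 to 95% of random lists in 7 cell types, and between mice 3 and 5 in 5. In 8 of 9 cell types a list of glucocorticoid targets not looked at before lay above 95% of random lists of the same expression, and over all cells the median log2 ratio was 0.32, with 12 of 14 genes higher. In intercalated cells the ratio was -0.22. Another time of day for mouse 4 cannot be told apart: the median log2 ratio of 8 clock output genes was 0.844, between the values set for and against it, with Arntl at -0.57. Over all cells Dbp was 5.54, 45.4 and 41.5 CPM and Arntl 14.2, 6.54 and 6.19 CPM in mice 3, 4 and 5, so in these clock genes mouse 3 stood apart while mice 4 and 5 were close. What would have given mouse 4 such a response was not tested, since the labels give nothing that sets it apart.

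Saa3, an acute phase protein, was 10.7, 18.3, 2.88, 139 and 3.95 CPM in mice 1 to 5 over all cells. Dbp was 16.2 CPM in mouse 1 and 61.5 CPM in mouse 2.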
